A study of Mus musculus with 11 samples.

How the data were processed

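Cells of the mouse esophagus were profiled by ATAC-seq, per the labels' protocols: sorted cells were lysed, nuclei were treated with Illumina transposase, DNA was purified and amplified by PCR, and libraries were size selected and sequenced as paired ends on a NovaSeq. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned to GRCm38/mm10 with Bowtie2 and cleared of duplicates with Picard, peaks were called with MACS2, and deepTools was used; versions and settings are not given in the sources used here. One list of intervals was used for each of the 11 libraries, in 10 columns without a header. The score values (column 5) were made by the authors with MACS2, per the submitters' processing notes, and were not used to rank intervals here. The fold enrichment values (column 7) were made by the authors with MACS2 over its local background, per the submitters' processing notes. The −log10 p-value and −log10 q-value columns (8 and 9) were made by the authors with MACS2, per the submitters' processing notes. The position of the summit within the interval (column 10) was likewise deposited by the authors. Numbers of reads are not given in the sources used here, so depth is unknown and no list could be scaled by it.

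All results were computed from these lists. Lines that repeat an interval for several summits were merged, chromosomes 1 to 19 and X were kept, and the intervals of all 11 lists were merged into 124941 regions (median width 693 bp). A region counted as occupied in a library where an interval overlapped it by at least 1 bp. Each region was assigned to the nearest protein-coding gene body within 100 kb, among 21631 genes of the GRCm38.p6 RefSeq table, and 111956 regions (89.6%) had one. That table gives neither strand nor transcription start sites. The planned distance to the nearest start site was therefore replaced by the distance to the gene body, and the planned 1 kb around a start site by 1 kb around either gene end. Coordinates are 1-based in GRCm38. A region was gained where it was occupied in 3 of 3 libraries of the first group and 0 of 3 of the second, and lost in the reverse case. Fixed-rule choices, gene lists and alternatives were written before the data were examined.

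Gene loci were tested with limma, with the variance trend on and the robust option off, on log2((occupied regions + 0.5) / (total occupied regions + 1) × 100000). The 15331 loci with a mean of at least 1 occupied region were tested, with the 3 adult groups in one fit. Benjamini-Hochberg adjustment was made within each comparison at 0.05. Adjusted p-values of genes are from this fit. Where all libraries of a group hold the same count at a locus, only the library totals set their spread, which can make p-values small. An increase here means more occupied regions in a locus, not a higher signal in any of them, and not expression. The 22 fixed lists were tested with camera at a preset correlation of 0.01 and at an estimated one, and with limma's fry. Splits of 3 against 3 and of the 9 adult libraries were counted exactly (10 and 280 splits). Embryo occupancy was compared with two-sided Fisher's exact tests across regions, with Wilson intervals of 95% on shares. In the held-out comparison each library of a group was left out in turn while regions were chosen on the remaining ones.

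Genes named in the text follow a rule fixed in advance: up to 10 per direction with the largest absolute log2 change among those with an adjusted p under 0.05 and non-overlapping groups, without unnamed predicted genes; up to 4 members of each fixed list with the largest absolute log2 change; and always Sox9, Gli1, Ptch1, Smo, Krt5, Krt14, Trp63, Sox2, Klf4, Epcam, Krt8 and Foxa2. Up to 5 regions per set were named by the median rank of the authors' −log10 p-value within their lists. No log2 change is given where all libraries of a group were at 0. Some results that the rule covers are not reported here.

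Before use, the steps were tested on simulated data. For SmoM2 against WT, 200 loci were changed and 14304 loci passed the filter and were tested. Among tested loci, limma recovered 7 of 88 changed 2-fold (8%) and 46 of 86 changed 4-fold (53.5%), and called 1 unchanged locus. The simulation gave all regions of a locus the same chance of being occupied, which the data do not follow. These rates may therefore not carry over to the data, where smaller changes may still go uncalled. The region step recovered all of the regions made to be gained or lost.

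Alternatives covered stricter intervals (−log10 q of at least 5), lists of equal length (69026 intervals, the top ones of each), 501 bp windows, autosomes only, occupancy in 2 of 3 libraries, other pseudocounts (1 and 0.25) and filters, a 20 kb locus, covered base pairs (pseudocount 346.5 bp), no scaling, only the 6 libraries compared, a replicate block, and leaving out each library. A required overlap of 50% changes nothing by construction, since every region is merged from the intervals it is compared with. Chosen after seeing the data were a fit with Y-linked intervals as a covariate, removal of intervals over 10 kb, matching on within-list rank, random gene lists with as many regions per locus, and equal lists with each library, or 1 library of each group, left out. Motif tests were planned but not run, because they need the genome sequence, which was not used here. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1.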

Results

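Open chromatin was mapped in sorted cells of the mouse esophagus by ATAC-seq, in which a transposase inserts sequencing adapters where DNA is accessible. The 11 libraries fell into 4 groups. In the wild-type group (WT, 3 libraries) cells were sorted for low levels of EpCAM, an epithelial adhesion protein. In Krt5-SmoM2 mice (SmoM2, 3 libraries) cells were sorted for high EpCAM. SmoM2 is an activated form of Smoothened, the receptor that switches on Hedgehog signaling, and Krt5 is a keratin of basal epithelial cells. The third group carried the same transgene together with a floxed Sox9 gene, which encodes a transcription factor of many progenitor cells (SmoM2-Sox9cKO, 3 libraries, high EpCAM). The last group was esophagus of embryonic day 13 from Krt8YFP embryos, sorted on YFP (Embryo, 2 libraries). For each library a list of intervals called as open was analysed. The 9 adult lists held 69116 to 87966 intervals, covering 55.3 ± 3.14 Mb in WT (mean ± SD, n = 3), 56.3 ± 5.72 Mb in SmoM2 and 55.5 ± 5.61 Mb in SmoM2-Sox9cKO. The Embryo lists were shorter, with 24927 and 14281 intervals over 15.4 and 8.22 Mb, and lay closer to genes: 42.4% and 52.9% of their intervals were within 1 kb of a gene end, against 19.4% ± 0.873 in WT. Merging all lists gave 124941 regions, of which 44519 were occupied in all 9 adult libraries. Numbers of reads are not given in the sources used here, so the depth behind each list is unknown. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples. The EpCAM gate differed between WT and both other adult groups, so genotype and gate cannot be separated in comparisons with WT. Intervals at Y-linked genes also differed between and within the adult groups, and the sex of the animals is not given in the labels.

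The targeted gene was examined first. At the Sox9 locus on chromosome 11 (GRCm38), WT held 9.0 ± 2.0 occupied regions, SmoM2 10 ± 1.0 and SmoM2-Sox9cKO 10.3 ± 1.53 (mean ± SD, n = 3 each). The region at 11:112781281-112783193, which overlaps the start coordinate of the Sox9 gene body (11:112782210-112787757), was occupied in all 11 libraries. The part of Sox9 removed by recombination is not given in the labels, so presence of this region does not check the deletion. A region at 11:112767207-112768073, outside the gene body, was occupied in 3 of 3 SmoM2, 2 of 3 SmoM2-Sox9cKO and 0 of 3 WT libraries, and one at 11:112833768-112834587 in 3 of 3, 3 of 3 and 0 of 3. Both were picked after their values were seen, as were the single regions given for Ptch1, Smo and Epcam.

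Libraries of one group resembled each other more than libraries of different groups. The Jaccard index, the share of occupied regions that a pair of libraries has in common, averaged 0.754 within adult groups and 0.653 between them, a difference of 0.102 that was the highest of all 280 splits of the 9 libraries (one-sided exact permutation p = 0.00357). WT and SmoM2 were farthest apart (0.609 ± 0.02, SD over 9 pairs). SmoM2 and SmoM2-Sox9cKO were closest (0.715 ± 0.026), and WT and SmoM2-Sox9cKO had 0.634 ± 0.015. The lowest similarity was to Embryo, at 0.197 ± 0.043 for WT, 0.188 ± 0.042 for SmoM2 and 0.192 ± 0.041 for SmoM2-Sox9cKO, and the Embryo libraries had 0.468 with each other. The Embryo lists are much shorter than the adult ones, which limits how high this index can be. On average WT libraries held 75.2% of the regions of Embryo 1 and 84.2% of those of Embryo 2.

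The comparison of SmoM2 with WT addressed how chromatin in the esophagus differs when Hedgehog signaling is switched on in Krt5-expressing cells. Several of the largest increases in SmoM2 on the log2 scale were at loci with no open region in any WT library, where the pseudocount helps set the change. Kit, a receptor tyrosine kinase of stem and progenitor cells, held 8.0 ± 1.73 occupied regions in SmoM2 and was listed at 0 in WT (n = 3 each, adjusted p = 3.91e-06). Wdr72, a gene needed for tooth enamel, held 10.3 ± 1.53 against 0 (adjusted p = 9.02e-07), Pdgfd, a platelet-derived growth factor, 12.3 ± 2.52 against 0 (adjusted p = 0.00524), and Tmem26 8.67 ± 0.58 against 0 (adjusted p = 2.27e-06). Ptprd, a receptor tyrosine phosphatase, rose from 1.33 ± 0.58 to 27.0 ± 3.61 regions (log2 change 3.82, SE 0.18, adjusted p = 5.41e-06). In the other direction, Oprm1, the mu opioid receptor, held 6.0 ± 1.0 regions in WT and 0 in SmoM2 (adjusted p = 1.22e-07), and Cdh19, a cadherin, 4.67 ± 0.58 and 0 (adjusted p = 6.8e-07). Sox11, a transcription factor of embryonic progenitors, held 3.67 ± 1.53 in WT and 0 in SmoM2 (adjusted p = 0.00209). Pde7b, a cyclic AMP phosphodiesterase, fell from 15.7 ± 1.53 to 3.0 ± 2.65 (log2 change -2.60, SE 0.41, adjusted p = 0.00493). Among the other loci with the largest changes, Kcnip4, Adgrl4, Trap1a, Ugt8a and Unc13c were higher in SmoM2, and Grin3a, Sgip1, Nat8f3, Adamts13, Rftn1 and Kcnk10 were lower.

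**Figure D1:**
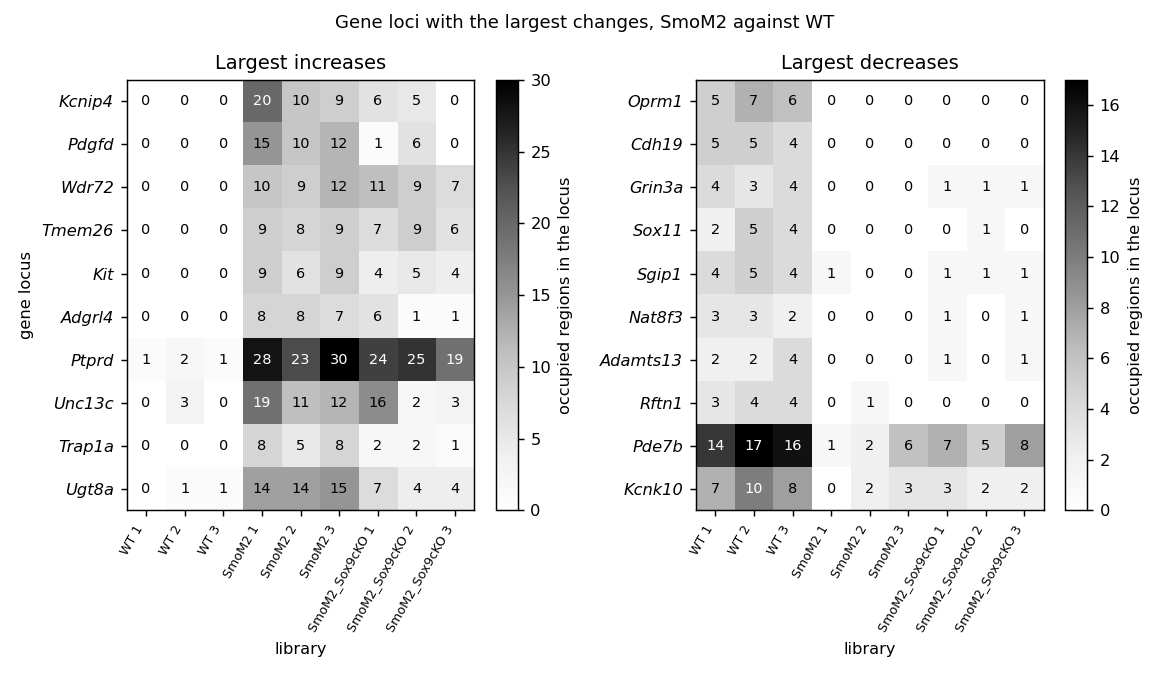
Heat map of occupied regions per gene locus in the 9 adult libraries (columns, grouped as WT, SmoM2 and SmoM2-Sox9cKO) for the 10 genes with the largest increases and the 10 with the largest decreases in SmoM2 against WT (rows). Each cell shows the number of occupied regions, for example 28, 23 and 30 at Ptprd in SmoM2 against 1, 2 and 1 in WT.

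Genes of the Wnt pathway were affected in both directions. Of 48 members tested, 5 rose, 5 fell and 38 did not pass (6 and 5 adjusted over the list alone). Wif1, a secreted Wnt inhibitor, rose from 1.0 ± 0.0 to 11.7 ± 1.15 regions (log2 change 2.89, SE 0.25, adjusted p = 0.000233), and Lgr5, a stem cell receptor for R-spondins, from 4.33 ± 0.58 to 13.3 ± 1.53 (log2 change 1.39, SE 0.16, adjusted p = 0.0012). The other increases were at Znrf3, Axin2 and Fzd1. Rspo1, an R-spondin ligand, fell from 2.67 ± 0.58 to 1.0 ± 0.0 (adjusted p = 0.00429), with Fzd2, Wnt7a, Sfrp1 and Nkd1. Members named without a value complete these counts and were chosen after their values were seen, here and in the lists that follow. Of 33 extracellular matrix and remodeling genes, 7 rose and 3 fell (7 and 4 adjusted over the list alone). Itgb8, an integrin that activates TGF-beta, rose from 2.67 ± 0.58 to 10 ± 0.0 (log2 change 1.62, SE 0.14, adjusted p = 0.000269), Col4a2, a basement membrane collagen, from 3.67 ± 0.58 to 11.7 ± 1.15 (log2 change 1.43), Cdh11, a mesenchymal cadherin, from 2.33 ± 0.58 to 10.7 ± 1.53 (log2 change 1.86) and Mmp13, a collagenase, from 1.0 ± 1.0 to 5.67 ± 1.53 (log2 change 2.17). Fn1, Lama5 and Loxl1 fell. Of 37 BMP and TGF-beta genes, 4 rose (Bmp6, Bambi, Bmpr1b, Bmp5), or 5 adjusted over the list alone, and Tgfb2, Bmp4, Ltbp1 and Tgfbr3 were among those that fell. The ligand gene Bmp6 went from 6.0 ± 0.0 to 14.3 ± 1.53 (log2 change 1.06, adjusted p = 0.000827), and the receptor gene Bmpr1b from 6.0 ± 1.73 to 18 ± 1.73 (log2 change 1.42, adjusted p = 0.00524).

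Most Hedgehog genes did not pass the test, nor did most loci, with 1690 of 15331 called over the genome. Of 31 pathway members and targets, Bcl2 and Foxc1 rose, Ccnd2 and Cdon fell, and 27 did not pass, with the same counts of 2 and 2 adjusted over the list alone. Foxc1, a forkhead factor, went from 4.67 ± 1.15 to 8.0 ± 1.0 (log2 change 0.61, adjusted p = 0.0432) and the cyclin gene Ccnd2 from 7.67 ± 0.58 to 5.33 ± 1.15 (log2 change -0.63, adjusted p = 0.0496). The Foxc1 call held in 9 of 21 alternatives and the Ccnd2 call in 7 of 21. Each held in 2 of the 9 alternatives that left out a library. Ptch1, the Hedgehog receptor and a classic target, held 9.67 ± 1.53 regions in WT and 13.3 ± 1.53 in SmoM2 (log2 change 0.33, SE 0.10, adjusted p = 0.0801), which missed the threshold. Single regions at Ptch1 differed in both directions: those at 13:63576007-63577044, 13:63592925-63594204 and 13:63672272-63672871, outside the gene body, were occupied in 3 of 3 SmoM2 and 0 of 3 WT libraries, while 13:63563153-63565354, inside it, and 13:63631564-63632169 were occupied in 3 of 3 WT and 0 of 3 SmoM2. Gli1, the transcriptional effector, held 2.33 ± 0.58 and 3.0 ± 0.0 regions in WT and SmoM2 (adjusted p = 0.488), and Smo 5.0 ± 1.0 and 6.33 ± 0.58 (adjusted p = 0.459), with one region in its gene body at 6:29743750-29744699 present in 3 of 3 SmoM2 and 0 of 3 WT.

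**Figure D2:**
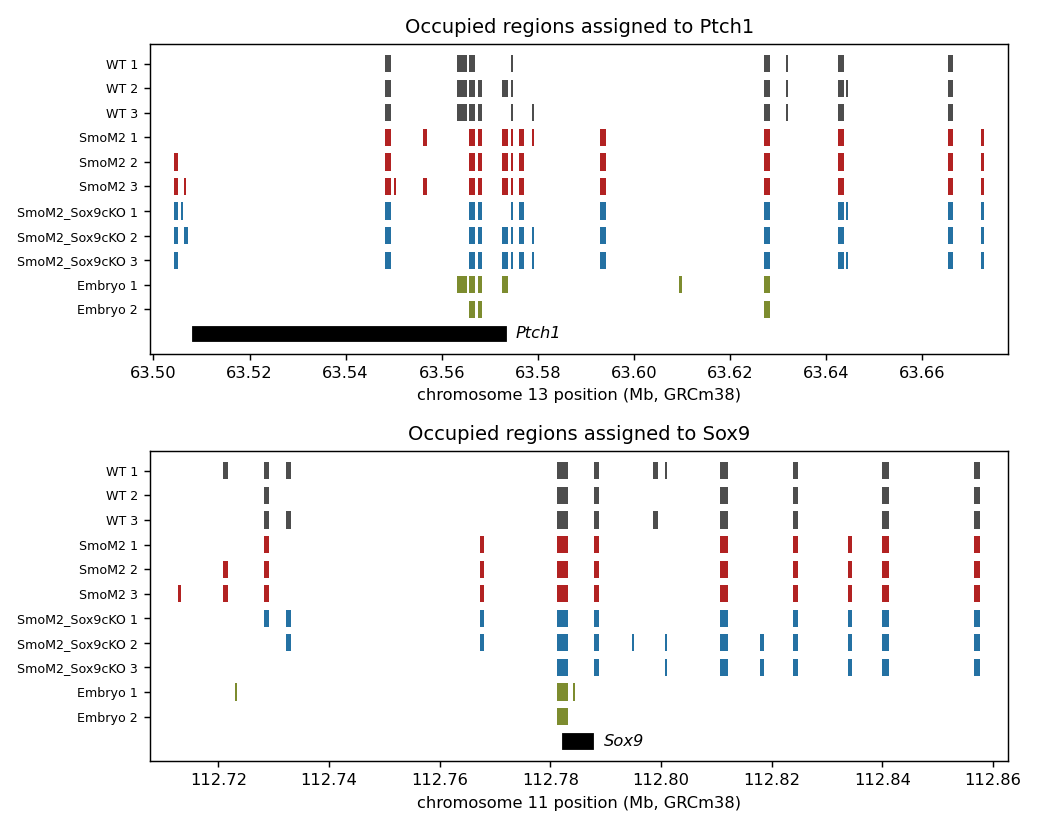
Occupied regions assigned to Ptch1 on chromosome 13 and to Sox9 on chromosome 11, drawn by GRCm38 position (horizontal axis) for each of the 11 libraries (vertical axis). The 3 SmoM2 libraries hold 13, 12 and 15 regions at Ptch1 against 8, 11 and 10 in WT.

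Most genes of the esophageal epithelium did not pass. Of 25 basal keratinocyte genes, Tfap2c alone fell and none rose (0 and 0 adjusted over the list alone; 1 up and 3 down at an unadjusted limma p under 0.05). Krt5 had 3.0 ± 1.0 regions in both groups. Krt14 had 4.33 ± 0.58 in WT and 5.33 ± 0.58 in SmoM2, and Trp63, the p63 gene of squamous progenitors, 30.3 ± 2.52 and 34.3 ± 6.51 (adjusted p = 0.444 and 0.764). Of 37 genes of squamous differentiation, Krt4, a keratin of the suprabasal esophagus, fell from 4.0 ± 0.0 to 2.67 ± 0.58 (log2 change -0.65, adjusted p = 0.0321), and Lor, a cornified envelope protein, from 4.0 ± 0.0 to 2.33 ± 0.58 (log2 change -0.81, adjusted p = 0.00635). Lor alone passed when adjusted over the list alone. None rose, against 2 up at an unadjusted limma p under 0.05. Of 38 foregut endoderm genes, Hhex alone rose (0 adjusted over the list alone), and Sox11 was among those that fell. Of 18 Sox genes, Sox5 rose from 13.3 ± 3.51 to 26.0 ± 3.61 (log2 change 0.84, SE 0.15, adjusted p = 0.00938) and Sox11 and Sox1 fell (2 and 3 adjusted over the list alone). Sox2 held 11.7 ± 0.58 and 12.7 ± 1.15 regions (adjusted p = 0.918). Of 32 columnar epithelium genes, Lgr5 rose and Cldn2, a claudin, fell from 4.0 ± 0.0 to 2.0 ± 0.0 (log2 change -0.97, adjusted p = 0.0105), with 1 and 1 adjusted over the list alone. Krt8, a keratin of simple epithelia, had 1.0 ± 0.0 in both groups, and Foxa2 3.33 ± 0.58 and 4.33 ± 1.15 (adjusted p = 0.616).

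Of 30 genes of hair follicle and basal cell carcinoma, Foxc1, Adamts1 and Runx1 rose and Edar, Msx2, Bmp4, Hoxc13 and Msx1 fell (5 and 6 adjusted over the list alone). Msx1, a homeobox repressor, went from 4.0 ± 1.0 to 1.33 ± 0.58 (log2 change -1.44, adjusted p = 0.00977), and Bmp4, a BMP ligand, from 15.3 ± 1.53 to 10 ± 1.0 (log2 change -0.72, adjusted p = 0.00332). Of 35 cell cycle genes, Cdkn2b, which encodes the inhibitor p15, rose from 7.33 ± 0.58 to 12.3 ± 0.58 (log2 change 0.59, adjusted p = 0.00791), and Rrm2, a subunit of ribonucleotide reductase, and Ccne1 fell (1 and 1 adjusted over the list alone). Of 25 Notch genes the ligand gene Dll1 fell from 10.7 ± 1.53 to 8.0 ± 1.0 (log2 change -0.51, adjusted p = 0.013) and none rose (0 and 1 adjusted over the list alone; 3 up at an unadjusted limma p under 0.05). Of 26 housekeeping genes Emc7 rose and Ppia fell, with the same 2 calls adjusted over the list alone.

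Epcam, whose product was used for the sort, held 9.33 ± 0.58 regions in EpCAM-low WT, 10.7 ± 0.58 in EpCAM-high SmoM2 (adjusted p = 0.717) and 13.7 ± 1.15 in SmoM2-Sox9cKO. One Epcam region, 17:87598556-87598928, was occupied in 3 of 3 WT and in none of the 6 libraries of the other adult groups. Markers of other cell types also moved between WT and SmoM2. Of 20 endothelial genes, Pecam1, Emcn and Cdh5 rose and Flt1 and Esam fell (3 and 2 adjusted over the list alone), with Cdh5 at 3.67 ± 0.58 and 6.67 ± 0.58 (log2 change 0.67, adjusted p = 0.00426) and Flt1 at 20.3 ± 2.08 and 13.7 ± 1.53 (log2 change -0.68, adjusted p = 0.00359). The Cdh5 difference turned to a log2 change of -0.12 when loci reached 20 kb (adjusted p = 0.718, range over its alternatives 0.000835 to 0.718). Of 15 fibroblast genes, Twist2, a mesenchymal transcription factor, rose from 0.67 ± 0.58 to 6.33 ± 0.58 (log2 change 2.59, adjusted p = 0.00222) with Zeb2, and Col6a3, Dpt and Tbx15 fell (2 and 4 adjusted over the list alone). Hand2, a neural crest factor, went from 9.33 ± 1.53 to 3.0 ± 1.73 (log2 change -1.77, adjusted p = 0.0216) and Snap25, a synaptic protein, from 4.33 ± 1.15 to 9.33 ± 0.58 (log2 change 0.93, adjusted p = 0.00253). They were the 2 calls among 14 neural genes, also adjusted over the list alone. Of 15 muscle genes Acta2 fell, of 15 immune genes Ptprc rose, of 12 lung and trachea genes Sftpb rose, and of 16 liver and brain genes Mog rose and Pdx1 fell, with the same calls adjusted over each list alone. None of 11 Langerhans and dendritic or 6 erythroid genes passed, with 1 up and 2 down among those 17 at an unadjusted limma p under 0.05, and none adjusted over the list alone. Intervals at 4 Y-linked genes also differed between these groups and within WT: 9 in each SmoM2 library, and 5, 0 and 0 in WT.

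Over the genome, 806 of 15331 loci rose and 884 fell in SmoM2 (limma, Benjamini-Hochberg adjusted p under 0.05). All of the called loci had non-overlapping groups, as did 25.8% of all tested loci, where chance gives 10%. Each locus was scaled by the total number of occupied regions of its library, which set the median log2 change at -0.123. The number that fell was 539 without WT replicate 3 and 572 without SmoM2 replicate 1, and with covered base pairs in place of regions 1273 rose and 1507 fell. Without scaling by the total 770 rose and 343 fell, and 470 and 221 loci were called in the same direction with it, without it and with lists of equal length. With presence of Y-linked intervals as a covariate, chosen after seeing the data, 393 rose and 343 fell, and the calls that ended include Unc13c, Kcnk10, Foxc1, Ccnd2, Krt4, Cldn2, Msx1, Dll1 and Hand2, and also Adamts1, Hoxc13, Sox1, Ppia, Emcn, Dpt, Col6a3, Acta2, Mog and Pdx1. No fixed list moved one way on balance (camera, lowest adjusted p = 0.848; limma's fry, lowest adjusted p = 0.083, for the hair follicle list), at the preset or an estimated correlation.

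At the level of single regions, 8637 were occupied in 3 of 3 SmoM2 and 0 of 3 WT libraries (gained) and 3887 the reverse (lost), 12524 in all against at most 680 in the other 9 splits of the 6 libraries. A design of 3 against 3 cannot give a share of splits under 0.1. Gained regions were mostly distal, with 3.37% within 1 kb of a gene end against 27.3% of those occupied in all 9 adult libraries, and 51.1% lay in a gene body. Lost regions were much alike, with 4.81% within 1 kb of a gene end and 50.5% in a gene body, so this does not set gained regions apart. The 5 gained regions ranked highest within the authors' lists were 2:46512061-46513274, 2:120959356-120960212 in Ubr1, 6:23743205-23744184 in Cadps2, 1:175453219-175454685 in Rgs7 and 1:157716866-157717722. The 5 lost regions ranked highest were 19:21990301-21991688, 4:46321457-46322528 in Gm12447, 10:6814161-6815377 in Oprm1, 8:116102550-116103244 and 11:9997054-9998347. With lists of equal length 6774 regions were gained and 4891 lost, and without WT replicate 1 there were 9178 and 6203.

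**Figure D3:**
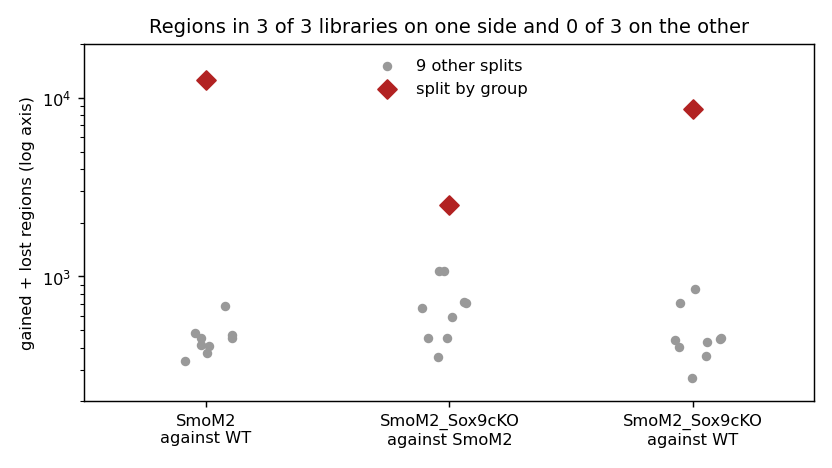
Regions gained plus lost (vertical axis, log scale) for each of the 10 splits of the 6 libraries into 3 and 3, in each of the 3 comparisons (horizontal axis). Red points are the split by group, at 12524, 2515 and 8677 regions, and grey points are the other 9 splits, at most 680, 1075 and 855.

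The comparison of SmoM2-Sox9cKO with SmoM2, both EpCAM-high, asked how open chromatin of SmoM2 cells differs when Sox9 is floxed. The labels give a strain (CD1) for WT and SmoM2 but none for SmoM2-Sox9cKO, so a difference in background cannot be separated from the Sox9 allele. The SmoM2-Sox9cKO samples are also numbered apart from those of WT and SmoM2, so a batch that goes with the group cannot be separated either. Chrm3, a muscarinic acetylcholine receptor, fell from 13.3 ± 2.52 to 1.67 ± 0.58 regions (log2 change -2.64, SE 0.23, adjusted p = 0.00321). Lama4, a laminin chain, held 3.67 ± 0.58 in SmoM2 and 0 in SmoM2-Sox9cKO (adjusted p = 2.65e-05), Nxph1, a neurexin ligand, 6.33 ± 1.53 and 0 (adjusted p = 0.00514), and Fam155a 6.67 ± 2.08 and 0 (adjusted p = 0.00912). Adamts18, a metalloprotease, fell from 5.0 ± 0.0 to 0.33 ± 0.58 (log2 change -2.87, SE 0.34, adjusted p = 0.0126). At Adamts18 WT held 5.33 ± 0.58 regions, whereas at Chrm3 the WT libraries held 1, 2 and 1 and at Lama4 none. Higher in SmoM2-Sox9cKO were Skint6, of an epidermal immunoglobulin family, with 3.33 ± 0.58 regions against 0 (adjusted p = 5.98e-07), and Alkbh5, an RNA demethylase, from 1.0 ± 0.0 to 4.67 ± 1.15 (log2 change 1.82, SE 0.24, adjusted p = 0.0152). The glutamate receptor subunit gene Grin3a was also higher, with 1.0 ± 0.0 against 0 (adjusted p = 0.00222). Its counts were equal within each group, so only library totals set its spread, and this p-value does not measure spread in occupancy. Pax2, a kidney and ear transcription factor, went from 0.67 ± 1.15 to 5.67 ± 0.58 (log2 change 2.91, adjusted p = 0.0355), a call made in 1 of 9 analyses that each left out a library, as were those at C2 and Ear1. Those at Pld5, Mef2c, Mmp10 and Mog were made in 2 of 9, and that at Olfr161 in 2 of 8. The other loci with the largest changes were Olfm1, Olfr161, Bicc1, C2, Six6 and Cntn6, which were higher, and Ear1, Pld5, Ear10, Sprr2d and Sprr2f, which were lower. The Ear, Sprr2, Skint and Olfr families hold near-identical copies, and how reads were shared among them is not given in the sources used here.

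Of the 22 fixed lists, 17 held no called gene in this comparison (limma), with 38 up and 12 down at an unadjusted p under 0.05 among their 390 tested members. The calls in the other lists were Nkd1, a Wnt inhibitor, which rose from 2.0 ± 0.0 to 4.0 ± 0.0 (log2 change 0.91, adjusted p = 0.0152), and Mmp10, Sprr2d, Mef2c and Mog, which fell. Mef2c, a muscle and neural crest factor, went from 6.67 ± 1.15 to 2.67 ± 0.58 (log2 change -1.12, adjusted p = 0.0386). Adjusted over the list alone, those 5 calls stood, Loxl1, Flt1, Col6a3 and Snap25 were added among those that rose, and Cdh11, Mmp7 and Sox5 among those that fell. Sox5 held 26.0 ± 3.61 regions in SmoM2 and 15.7 ± 2.31 in SmoM2-Sox9cKO (adjusted p = 0.112 over all loci), and Cdh11 10.7 ± 1.53 and 4.67 ± 2.08 (adjusted p = 0.134). The Hedgehog genes Ptch1, Gli1 and Smo had adjusted p of 0.781, 0.816 and 0.805, and the epithelial genes Krt5, Krt14, Trp63, Sox2, Klf4, Epcam, Krt8 and Foxa2 between 0.231 and 0.984. Sox9 itself had an adjusted p of 0.816. No list passed as a set moving in one direction (camera, lowest adjusted p = 0.537, for the fibroblast list at the preset correlation, and 0.831 at an estimated one; limma's fry, lowest adjusted p = 0.0626). In fry's test of change in either direction several did, with the lowest adjusted p, 2.76e-06, in the Wnt, matrix and squamous lists. The liver and brain list passed it as well (fry, adjusted p = 0.000807). In SmoM2 against WT the housekeeping list also passed it (fry, adjusted p = 3.94e-06). This test sets a list against no change rather than against other genes, so passing it does not set a list apart. Intervals at the 4 Y-linked genes numbered 8, 10 and 0 in the SmoM2-Sox9cKO libraries.

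In all, 65 loci rose and 67 fell in SmoM2-Sox9cKO against SmoM2 (limma). Non-overlapping groups made up 11.5% of tested loci, against 10% by chance. These counts depended on single libraries and settings: 8 and 20 without SmoM2-Sox9cKO replicate 3, 12 and 20 without SmoM2 replicate 1, 29 and 21 without SmoM2 replicate 2, 105 and 71 without SmoM2 replicate 3, and 13 and 21 with Y-linked intervals as a covariate, under which the calls at Pax2, Olfm1, C2, Cntn6, Ear1, Pld5, Ear10, Nkd1, Mmp10, Mef2c and Mog ended. Of the calls with lists of equal length, 96 and 72, only 19 in each direction were among those 65 and 67. At single regions, 847 were gained and 1668 lost, 2515 in all against at most 1075 in the other 9 splits. With lists of equal length 1080 were gained and 1272 lost. The highest ranked lost regions were 4:33039411-33040587 in Ube2j1, 11:12375015-12375277 in Cobl, 18:11288593-11288845, 13:10636658-10637420 and 14:43840257-43841506 near Ear1. The highest ranked gained regions were 12:69389677-69390496 near Arf6, 2:147747240-147748248, 2:147767670-147768434, 4:112124383-112125657 in Skint4 and 11:82086730-82087473 near Ccl12. Leaving out a library moved both counts, to between 1071 and 1965 gained and between 1918 and 3445 lost.

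Against WT, SmoM2-Sox9cKO showed many of the same differences as SmoM2. Wdr72 held 9.0 ± 2.0 regions, Tmem26 7.33 ± 1.53 and Kit 4.33 ± 0.58, all listed at 0 in WT (adjusted p = 9.71e-07, 3.31e-06 and 1.74e-05). Ptprd rose from 1.33 ± 0.58 to 22.7 ± 3.21 (log2 change 3.63, SE 0.18, adjusted p = 1.13e-05). Ccl2, a chemokine that attracts monocytes, rose from 0.33 ± 0.58 to 5.33 ± 1.53 (log2 change 2.92, SE 0.42, adjusted p = 0.00399). Oprm1 and Cdh19 were at 0 in SmoM2-Sox9cKO as well (adjusted p = 1.41e-07 and 5.98e-07), and Sox11 fell from 3.67 ± 1.53 to 0.33 ± 0.58 (log2 change -2.52, SE 0.41, adjusted p = 0.00721). Ptch1 rose from 9.67 ± 1.53 to 14.0 ± 1.0 (log2 change 0.46, SE 0.10, adjusted p = 0.0307), a call that held in 11 of 21 alternatives. The 3 Ptch1 regions gained in SmoM2 were also occupied in 3 of 3 SmoM2-Sox9cKO libraries. Further loci with the largest changes were Ifi209, Rtl1, Nox3, Glp2r and Prss39, which were higher, and Sprr2f, Rftn1, Adamts18, Dcdc5, Fmo9, Samt3 and Upb1, which were lower.

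By list, calls against WT were spread over 18 of the 22. In the Wnt list Lgr5 (from 4.33 ± 0.58 to 13 ± 3.61, log2 change 1.39, adjusted p = 0.0015), Wif1 (log2 change 2.24, adjusted p = 0.00137) and Znrf3 rose and Fzd8 and Rspo1 fell (6 and 2 adjusted over the list alone). Among matrix genes Itgb8 (log2 change 1.54, adjusted p = 0.000501), Col4a2 (log2 change 1.13, adjusted p = 0.000188), Col4a1 and Mmp11 rose and Fn1, Mmp10 and Mmp7 fell (7 and 6). Among BMP and TGF-beta genes Bmp6, Bmpr1b and Bmp5 rose and Tgfb2, Bmp4 and Ltbp1 fell (3 and 3), with the ligand gene Tgfb2 going from 14.3 ± 0.58 to 7.0 ± 1.0 (log2 change -1.05, SE 0.10, adjusted p = 0.000517). In the Hedgehog list Ptch1 rose and Cdon fell (1 and 2), and in the hair follicle list Ptch1 and Runx1 rose and Edar, Twist1, Msx2 and Bmp4 fell (5 and 7). E2f7, a repressor of cell cycle genes, fell from 7.33 ± 0.58 to 3.33 ± 0.58 (log2 change -1.10, adjusted p = 0.00434) and Cdkn2b rose, the calls among cell cycle genes (1 and 1). Lgr5 rose and Agr2 and Cldn2 fell among columnar genes (2 and 2), Hhex rose and Sox11 fell among foregut genes (0 and 1), Sox11 fell among Sox genes (0 and 1), Sprr2a1 rose and Sprr2d fell among squamous genes (1 and 1), and Tfap2c fell among basal genes (0 and 0). Among other cell types, Pecam1, Egfl7, Emcn, Tek and Cdh5 rose and Esam fell in the endothelial list (6 and 1), Twist2 and Zeb2 rose and Twist1 fell in the fibroblast list (2 and 1), Snap25 rose (log2 change 1.45, adjusted p = 0.000374) and Hand2 fell in the neural list (1 and 1), and Mef2c, Acta2 and Cnn1 fell in the muscle list (1 and 3). Cd83, Sftpb and Emc7 were single increases in the Langerhans and dendritic, lung and trachea, and housekeeping lists (1, 1 and 0). Pairs in parentheses are counts up and down adjusted over the list alone, and the last set gives increases only. The immune, erythroid, Notch, and liver and brain lists held no call among 62 members (limma), with 3 up and 3 down at an unadjusted p under 0.05.

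Over all loci 614 rose and 529 fell (limma), or 513 and 260 without scaling (with Y-linked intervals as a covariate the calls at Cldn2, Emc7, Fzd8, Hhex, Mef2c, Tek, Tfap2c and Twist1 ended), and 309 and 147 were called in the same direction with scaling, without it and with lists of equal length. The number that fell was 337 without SmoM2-Sox9cKO replicate 2 and 349 without WT replicate 2, and with covered base pairs 1052 rose and 1073 fell. Non-overlapping groups made up 22.1% of tested loci, against 10% by chance. At single regions 5322 were gained and 3355 lost, 8677 in all against at most 855 in the other 9 splits, and with lists of equal length 4556 and 3774. The highest ranked were 13:120321371-120321638 near Tcstv3 among those gained and 12:104718814-104719791 in Dicer1 among those lost, and 2:46512061-46513274 was among the 5 highest ranked gained regions here as in SmoM2 against WT. Without WT replicate 1 the counts drew level, at 5779 and 5652, without SmoM2-Sox9cKO replicate 1 they were 6535 and 5426, and without SmoM2-Sox9cKO replicate 3 they were 8416 and 4037. The 2 comparisons with WT shared 477 increased loci (32.3 for independent lists) and 342 decreased loci (30.5 for independent lists). Across loci their log2 changes had r = 0.761 and a covariance of 0.172, against 0.502 and 0.028 in simulations of unchanged groups that share the same WT libraries. The 3 WT libraries cannot be split into parts of at least 2, so part of the excess of shared loci over independent lists may come from the shared controls.

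Regions gained in SmoM2 were sorted by their occupancy in the SmoM2-Sox9cKO libraries. Of the 8637, 3877 (44.9%) were occupied in all 3 SmoM2-Sox9cKO libraries and 1155 (13.4%) in none. The second count was 1757 without SmoM2 replicate 1, 2439 without SmoM2 replicate 2, 1760 without SmoM2-Sox9cKO replicate 1 and 1932 without SmoM2-Sox9cKO replicate 2. Chrm3, Nxph1 and Ugt8a had 5 of the 1155 regions each. Sox5, Fam155a and Pdgfd had 4, and Bmp6, Gli3, a Hedgehog transcription factor, and Lama4 had 3. These genes were chosen after their values were seen. Of the 3887 lost regions, 308 (7.9%) were occupied in all 3 SmoM2-Sox9cKO libraries and 2216 (57.0%) in none. Because regions chosen for being open in SmoM2 are partly chosen by chance, a held-out library served as the reference. Regions occupied in 2 SmoM2 and no WT libraries were occupied in 83.3% ± 11 of cases in the held-out SmoM2 library (85.0%, 71.6% and 93.3%) and in 61.8% ± 12.9 in SmoM2-Sox9cKO (68.0%, 70.3% and 47.0%), a difference of 21.5 percentage points (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). Regions occupied in 2 WT and no SmoM2 libraries were occupied in 74.5% ± 10.4 of cases in the held-out WT library and in 21.8% ± 5.59 in SmoM2-Sox9cKO, a difference of 52.7 points (exact p = 0.1). The difference for gained regions was 14.1 points without SmoM2-Sox9cKO replicate 3, where SmoM2-Sox9cKO averaged 69.2% ± 1.62 (n = 2).

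**Figure D4:**
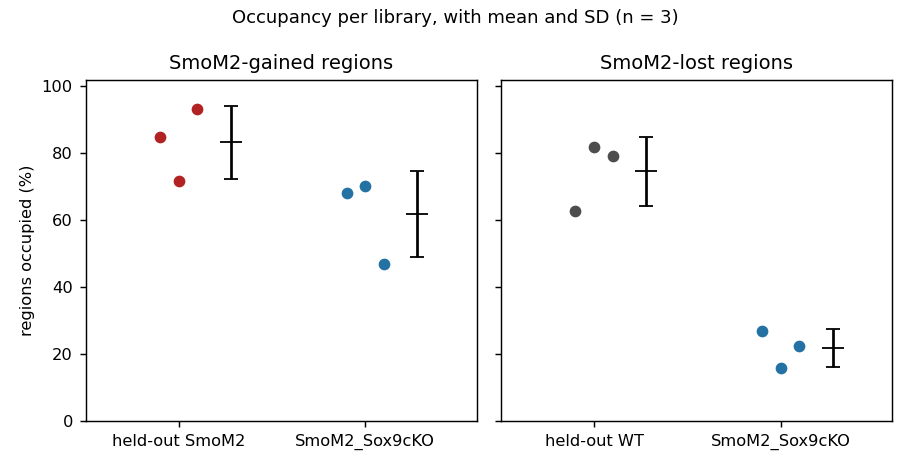
Share of regions occupied (vertical axis, percent) in each library (points), with the mean and SD of each group, for regions gained in SmoM2 (held-out SmoM2 against SmoM2-Sox9cKO libraries) and lost in SmoM2 (held-out WT against SmoM2-Sox9cKO libraries). SmoM2-Sox9cKO lies at 47.0% to 70.3% for gained regions and at 15.9% to 27.0% for lost regions.

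The Embryo libraries were used to ask whether regions opened in SmoM2 are open in the embryonic esophagus. Few were in the short Embryo lists, whose depth is unknown. Embryo 1 occupied 370 of the 8637 gained regions (4.28%, 95% Wilson interval 3.88 to 4.73) and 114 of the 3887 lost regions (2.93%, 2.45 to 3.51), against 36.8% of the regions open in all 9 adult libraries. The odds ratio of gained against lost was 1.48 (1.19 to 1.85, Fisher's exact test across regions, p = 0.000247). Embryo 2 occupied 1.64% and 0.9%, with an odds ratio of 1.84 (1.26 to 2.75, Fisher's exact p = 0.001), and of 6.99 (2.26 to 35.06, exact p = 2.91e-05) with intervals of −log10 q of at least 5, where 51 of 6770 gained and 3 of 2767 lost regions were occupied. Regions are not independent replicates. Without SmoM2 replicate 1 the odds ratio in Embryo 2 was 1.27 (exact p = 0.15). Kit, Wdr72, Ugt8a, Mical3 and Ptprr each had 3 of the 413 gained regions that either Embryo library occupied, and Chrm3 and Mecom, a zinc finger transcription factor, each had 2 of the 99 that both occupied. These genes, too, were picked after their values were seen. Gained regions absent from all SmoM2-Sox9cKO libraries and those present in all of them were occupied in Embryo 1 at 4.59% and 4.44%, an odds ratio of 1.04 (0.74 to 1.43, exact p = 0.808), and in Embryo 2 at 1.56% and 1.73%, an odds ratio of 0.90 (0.5 to 1.54, exact p = 0.795). Without SmoM2-Sox9cKO replicate 2 these odds ratios were 0.73 and 0.59 (exact p = 0.0293 and 0.0304). With whole lists no difference between the adult groups in closeness to Embryo passed, though 3 libraries per group may miss a small one. Of the regions of Embryo 1, WT libraries held 75.2% ± 2.00, SmoM2 77.2% ± 1.09 and SmoM2-Sox9cKO 75.8% ± 1.80 (exact permutation p = 0.361). Of those of Embryo 2 they held 84.2% ± 1.77, 86.1% ± 1.06 and 85.1% ± 0.706 in the same order (exact permutation p = 0.243).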

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

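The counts of other splits, the analysis with 1 library of each group left out and the analysis without the SmoM2-Sox9cKO library that lacks Y-linked intervals were chosen after the results were seen; the other tests in this part had their predictions written after the gained and lost counts and the Embryo shares were known but before the deciding values were. Intervals at 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) lie outside the chromosomes used in the comparisons and were singled out because they went beyond the level in WT. They numbered 9, 9 and 9 in SmoM2 and 8 and 10 in SmoM2-Sox9cKO replicates 1 and 2, against 0 in SmoM2-Sox9cKO replicate 3, 5, 0 and 0 in WT, and 0 in both Embryo libraries. Xist, which is expressed from the inactive X chromosome, held 1, 4 and 5 intervals in WT, 1, 2 and 3 in SmoM2, 3, 3 and 4 in SmoM2-Sox9cKO, and 1 and 0 in Embryo. Adult libraries with Y-linked intervals held 1 to 3 at Xist and those without held 4 or 5. The sex of the animals is not given in the labels, and no explanation of this pattern was tested.

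More regions were gained than lost in SmoM2 against WT, 8637 against 3887, a ratio of 2.22. Longer SmoM2 lists are a technical explanation. With lists of equal length the ratio was 1.38, above the bound of 1.2 set for excluding list length as the whole cause. With 1 library of each group also left out, which keeps the groups equal in size, it ranged from 1.13 to 1.24 over the 9 pairings. Fewer libraries loosen the definition of gained and lost, which raised gained regions from 6774 to at least 8637 and lost regions from 4891 to at least 7052. These ratios can therefore not be set against that bound. List length stays open as part of the cause. Genotype and the EpCAM gate also remain open, and as they go together in these groups they cannot be told apart. Intervals at Y-linked genes differed between these groups as well, at 9, 9 and 9 in SmoM2 and 5, 0 and 0 in WT. Whether this difference bears on the ratio was not tested.

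Regions gained in SmoM2 were less often occupied in SmoM2-Sox9cKO than in a held-out SmoM2 library. This could mean that part of them needs Sox9, or goes with another background strain or a batch, neither of which was tested. The lowest held-out SmoM2 share lay 1.3 percentage points above the highest SmoM2-Sox9cKO share. That order was predicted if selection of regions on the SmoM2 libraries were not the cause, and a held-out library took no part in choosing its regions. The gap was less than the larger SD of the groups, a bound that the prediction did not include. Spread between libraries could thus give this order, and the matter stays open. With equal lists the difference was 19.9 points in place of 21.5 and the gap 4.4, so shorter lists account for little of the difference. The predicted order was met here too, in a setting where no adult list was shorter than another. The gap is again under the SD, so spread between libraries could give this order as well. Depth, which is unknown, was not made equal. With intervals of −log10 q of at least 5 the groups overlapped, with a gap of -1.6 points (exact permutation p = 0.2 for the difference of 18.4 points). Without the SmoM2-Sox9cKO library that lacks Y-linked intervals the difference was 14.1 points, while the gap stayed at 1.3 by construction, since that library has the lowest share, so the gap decides nothing about it.

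Gained regions were more often occupied in Embryo than lost regions. If gained regions only held stronger peaks, matching gained and lost regions on rank within the lists would remove the difference. The matched odds ratio was 1.4 in Embryo 1 (1.09 to 1.81, Fisher's exact p = 0.00784) and 1.67 in Embryo 2 (1.07 to 2.62, Fisher's exact p = 0.0212), which argues against peak strength as the whole cause. This rests on a single random draw of matched regions and on tests across regions, which are not independent replicates. Without SmoM2 replicate 1 the unmatched odds ratio in Embryo 2 was 1.27 (Fisher's exact p = 0.15). The Embryo lists are short and of unknown depth, so a region missing from them need not be closed in the embryo. The EpCAM gate and the sort on YFP remain open as untested explanations.

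For the 6-library comparisons, the grouping was the 1 split of 10 with the most called loci in each case: 1690 against at most 1 elsewhere for SmoM2 and WT, 132 against 9 for SmoM2-Sox9cKO and SmoM2, and 1143 against 1 for SmoM2-Sox9cKO and WT. It was also the 1 of 10 with the most gained and lost regions, 12524 against 680, 2515 against 1075 and 8677 against 855. With 10 splits this share cannot go under 0.1. For the similarity of the 9 adult libraries the grouping was 1 of 280 splits, 0.102 against 0.0863 for the next, which argues against a chance assignment of libraries to groups.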

How the results depend on the processing

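The fit with Y-linked intervals as a covariate and the removal of intervals over 10 kb were among the tests chosen after seeing the data. Of the main results, 235 values were classed as unchanged, 53 as moved, 1 as weaker, 1 as stronger and 1 as reversed. Counts were classed by their distance from the main count, not by direction or threshold. Settings that change nothing by construction are included. Not every turn of direction was classed as reversed. For gained regions absent from against present in SmoM2-Sox9cKO, equal lists moved the Embryo 1 odds ratio from 1.04 to 0.87. In Embryo 2 that odds ratio moved from 0.9 to 1.16. Of named genes called changed, 2224 values stayed called, 460 lost the call and 1 turned direction, and of those not called 154 became called and 4038 did not. Occupancy in 2 of 3 against 0 of 3 libraries gave 14216 gained and 8090 lost regions for SmoM2 and WT, 3204 and 5032 for SmoM2-Sox9cKO and SmoM2, and 10630 and 7465 for SmoM2-Sox9cKO and WT. Covered base pairs gave 1273 loci up and 1507 down, 104 and 118, and 1052 and 1073 in the same order. Without scaling, loci down were 343 for SmoM2 and WT and 260 for SmoM2-Sox9cKO and WT. With the Y-linked covariate they were 393 up and 343 down for SmoM2 and WT and 13 and 21 for SmoM2-Sox9cKO and SmoM2. That last comparison gave 32 and 23 with a mean of at least 3 regions, 1.0e+02 (to 2 digits) and 122 without a filter, 18 and 25 with stricter intervals, and 29 down with only the 6 libraries. Cdh5 turned to a log2 change of -0.12 in SmoM2 with a 20 kb locus (adjusted p = 0.718, range over its alternatives 0.000835 to 0.718). The cause was not tested.

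Leaving out each library in turn gave, for SmoM2 and WT, 9178 to 12071 gained and 4319 to 6203 lost regions and 572 to 870 loci up and 539 to 845 down; for SmoM2-Sox9cKO and SmoM2, 1071 to 1965 and 1918 to 3445 regions and 8 to 105 and 20 to 72 loci; for SmoM2-Sox9cKO and WT, 5779 to 8416 and 3776 to 5652 regions and 423 to 599 and 337 to 526 loci. Fewer libraries widen the region counts by construction. The Jaccard difference ranged from 0.0900 to 0.117, and the held-out differences from 14.1 to 25.8 and from 49.8 to 55.3 points. Embryo odds ratios of gained against lost regions ranged from 1.24 to 1.85 in Embryo 1 and from 1.27 to 2.36 in Embryo 2, the lowest (exact p = 0.15) without SmoM2 replicate 1. Those of regions absent from against present in SmoM2-Sox9cKO ranged from 0.73 to 1.25 and from 0.59 to 1.43; the lowest values, without SmoM2-Sox9cKO replicate 2, reversed the direction in Embryo 1 (exact p = 0.0293 and 0.0304). The cause was not tested.

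Deviations from the group mean had correlations of -0.065 to 0.08 between libraries with the same replicate number, and of -0.116 to 0.115 between the others. No common deviation by replicate number was thus seen at gene loci. This cannot show whether the numbers pair the libraries. With a replicate block, SmoM2-Sox9cKO against SmoM2 gave 37 loci up and 38 down, SmoM2 against WT 812 and 874, and SmoM2-Sox9cKO against WT 588 and 453, and no list passed in camera. The block's exact sign-flip test of the held-out differences (21.5 and 52.7 points) gave p = 0.25, the smallest that 3 pairs allow. Motif alternatives were not run. Without read counts, how far depth limits any of these values is unknown.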

Other observations

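The comparison of long genes, the random gene lists and the counts per stretch of chromosome in this part were chosen after the results were seen; the test around Sox9 had its prediction written before its value was known. Among genes with many changed regions, Ptprd held 42 regions over its locus (4:75941237-78211742), of which 19 were gained and 0 lost in SmoM2 against WT, and 0 of these 19 were absent from all SmoM2-Sox9cKO libraries. Wdr72 (9:74110331-74283203) held 14 regions, 8 of them gained and 0 absent from all SmoM2-Sox9cKO libraries. Esrrg, an orphan nuclear receptor gene (1:187608510-188214885), held 31 regions with 8 gained, and 4 of these were occupied in no SmoM2-Sox9cKO library. Dpp10 (1:123332138-124845815) had 5 gained of 21, with 4 in no SmoM2-Sox9cKO library. Gli3, a Hedgehog transcription factor gene (13:15463723-15730026), had 5 gained and 2 lost of 30, and 3 of the gained ones were in no SmoM2-Sox9cKO library. Mecom (3:29951296-30509759) had 9 gained and 6 lost of 63, and 10 of its regions were occupied in Embryo 1. These genes were chosen after their values were seen.

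Regions gained in SmoM2 lay at longer genes than lost regions. Of gained regions with a gene, 1413 of 7096 (19.9%) had a nearest gene over 300 kb, against 498 of 3387 (14.7%) of lost regions (odds ratio 1.44, 1.29 to 1.62, two-sided Fisher's exact test across regions, p = 6.7e-11). Regions at one gene share its length and are not independent replicates, which this test does not allow for. The gained regions lay at 3861 genes and the lost ones at 2459. The median length of the nearest gene was 97.5 kb for gained and 74.6 kb for lost regions, against 47.3 kb for those open in all 9 adult libraries. Regions with no gene within 100 kb made up 17.8% of gained, 12.9% of lost and 23.4% of the gained regions that were in no SmoM2-Sox9cKO library. Of the fixed lists, fibroblast genes had 18 of 141 regions gained (12.8%, random lists 6.04%, permutation p = 0.049, adjusted p = 0.4) and basal keratinocyte genes 19 of 495 (3.84%, random lists 7.34%, p = 0.023, adjusted p = 0.4). Neither passed in this two-sided permutation over 10000 random lists, which were matched on regions per locus.

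Some regions set SmoM2-Sox9cKO apart from both other adult groups: 251 were occupied in 3 of 3 SmoM2-Sox9cKO and 0 of 6 other libraries, and 186 the reverse. A hypothesis tested here is that a chromosome segment carried along with the Sox9 allele brings sequence variants that change mapping. Such regions would then be more frequent around Sox9. Within 20 Mb of Sox9 they were 8 of 2786 (0.29%), against 392 of 113802 (0.34%) on other autosomes, a ratio of 0.83 (0.36 to 1.66, two-sided Fisher's exact test across regions, p = 0.743). That argues against such a segment as the source of these regions. A different background strain over the whole genome stays open, since the labels give none for SmoM2-Sox9cKO. A batch that goes with this group was not tested either. The stretch with the highest share was on chromosome 4 from 110 Mb, which holds the Skint genes, with 10 of 139 (7.19%), and the next was 2.38% on chromosome 14 from 40 Mb.

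The Embryo libraries alone occupied 4618 regions, and 20680 regions were occupied in a single adult library.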
